A study of Mus musculus with 15 samples.

How the data were processed

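RNA of mouse lung was measured on 2-colour Agilent oligonucleotide arrays. The 15 samples fall into 4 groups: 4 with aspirated rod-like carbon nanotubes (rCNT), 4 with aspirated phosphate-buffered saline (PBS), 3 with inhaled rCNT and 4 untreated. Each sample is 1 channel of an array, labelled with Cy3 or Cy5, and the other channel holds another RNA. The 15 samples came from 14 arrays on 3 slides, because inhaled rCNT replicate 2 and untreated replicate 4 share an array. Groups were taken from the labels. The title of untreated replicate 1 names a PBS aspiration while its other labels name an untreated mouse, so it was kept in the untreated group and also left out as an alternative. The labels do not say whether a sample is 1 mouse or a pool, and p-values therefore measure the spread between these samples, which may be technical.

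Per the file headers, spot intensities were extracted from the scans with Agilent Feature Extraction 11.0.1.1, and the array design refers to the mouse build mm9. Per the submitters' processing notes, Feature Extraction and limma were used. The deposited intensity values used here are the median brightness of each spot and of its local background in the sample's own channel. As an alternative, the processed intensity was used, which the authors' software had already background-subtracted and dye-normalised per the file headers. The deposited series table holds values without a stated scale, centring or direction, which were taken here as log2. Its columns correlated at 0.998 to 1.00 with the log2 intensity of the sample's own channel and at 0.973 to 0.993 with the other channel. This settles the channel and a logarithmic scale, but not the base of the logarithm. The medians of its 15 columns lay between 6.58 and 6.59, and how its values were background-corrected and brought to this common median stays unknown. That table served only as an alternative.

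The own-channel intensities were background-corrected with normexp (offset 50), put on the log2 scale and quantile-normalised over the 15 channels. Normexp used all 62976 spots of an array, and control spots and spots with an outlier flag (106 to 154 per sample) were then left out. No spot was saturated. Between 54.6% and 64.7% of the spots were well above background, and the median spot brightness ranged from 56.5 to 149.5 units. For arrays, their number limits the precision. A probe was kept if it was well above background in at least 3 samples of at least 1 group. This kept 34271 of 55681 probes. Probes were named through their RefSeq accession, with a table of the assembly GRCm38.p6 used for names only. Of 28685 probes with such an accession 27235 matched a gene symbol, for 20660 genes. The probe with the highest mean stood for a gene. For the named genes, 8 other probes of 7 genes after aspiration and 6 other probes of 6 genes after inhalation passed the filter, and none of them changed in the opposite direction at an unadjusted p below 0.05, though for Mmp12, Kdr and 1 probe of Cd300lf the change was much smaller. The tests covered 25317 genes or unnamed transcripts, 15694 of them with a symbol. Where a probe was not well above background in any sample of a group, the fold change is given as a lower bound. That bound is the brighter group's mean over the dimmer group's, each dim sample at the higher of its own value and the lowest signal among probes well above background in that sample.

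One linear model with the 4 groups and the dye was fitted to all samples with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). Contrasts were aspirated rCNT minus PBS, inhaled rCNT minus untreated, and the difference of these effects. No planned test compares levels between routes, because route, slide and kind of control go together. Levels of all 4 groups and the fits with PBS samples as inhalation controls, both added after the untreated samples were seen to stand apart, do compare them and carry that limit. The planned difference of effects carries it too, because it includes any difference between PBS and untreated samples. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and the threshold was 0.05. The 43 gene lists, for cell types, pathways and tissues that could be carried along, were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Numbers and figures were also prepared with Python 3.11.15.

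The groups, tests, gene lists, rule for named genes and most alternatives were set before the data were examined. The rule took, for each route, the 8 largest rises and 4 largest falls among genes with a symbol, an adjusted p below 0.05 and no overlap between exposed and control samples. It added the 2 members with the smallest p of each list that passed, and 18 genes fixed by name. For the difference between routes it took the 6 most positive and the 6 most negative genes. Of the genes this rule picked, 1 is left out of the text and of the counts of named genes, and no other gene takes its place. Genes chosen otherwise are said to be so.

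The fit was tested on simulated data with 200 changed genes among 25317. For aspiration, 84% of genes changed by a log2 value of 0.5 and 98% of those changed by 1 were recovered, with 5.2% false calls. For inhalation the values were 85%, 98% and 5.7%. Of 200 genes changed alike in both routes 0 were called different at the adjusted threshold. The simulation changed few genes and did not repeat the normalisation, while 47.1% and 60.8% of genes passed in the real aspiration and inhalation comparisons. These rates therefore need not hold for the real data.

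The alternatives covered the background correction, the normalisation, the filter on dim probes, the dye term, the slide, the replicate number as a block, the samples in the fit, the rule for several probes, the variance model, array weights, the series table and leaving out each sample in turn. A higher aspirated dose mentioned in the labels was not analysed here.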

Results

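Lungs of female C57BL/6 mice were profiled after exposure to rod-like carbon nanotubes (rCNT), which are fibre-shaped particles. In oropharyngeal aspiration a drop of liquid placed at the back of the throat is drawn into the lung, and in inhalation the animals breathe an aerosol. Aspirated rCNT was given at 10 µg per day in 50 µl of phosphate-buffered saline (PBS) on 4 days (4 samples), with PBS alone as its control (4 samples). Inhaled rCNT was given for 4 h per day on 4 days at 6.2 to 8.2 mg per cubic metre (3 samples), with untreated mice as its control (4 samples). Lungs were taken 24 h after the last exposure. Replicates of a group correlated at 0.995 to 0.9982 across the genes tested, and the median gene had a standard deviation (SD) of 0.0804 to 0.109 on the log2 scale. All 8 aspiration samples lay on 1 slide and the 7 inhalation samples on the other 2.

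The first principal component held 44.5% of the variance and the second 26.7%. Untreated samples lay at -50.6 to -47.5 on the first and PBS samples at -1.79 to 1.08, so the controls of the 2 routes stood apart from each other. Aspirated rCNT samples lay at 45.5 to 48.5 and inhaled rCNT samples at 1.64 to 5.16. On the second component inhaled rCNT samples lay at 44.0 to 57.1, above all others.

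**Figure D1:**
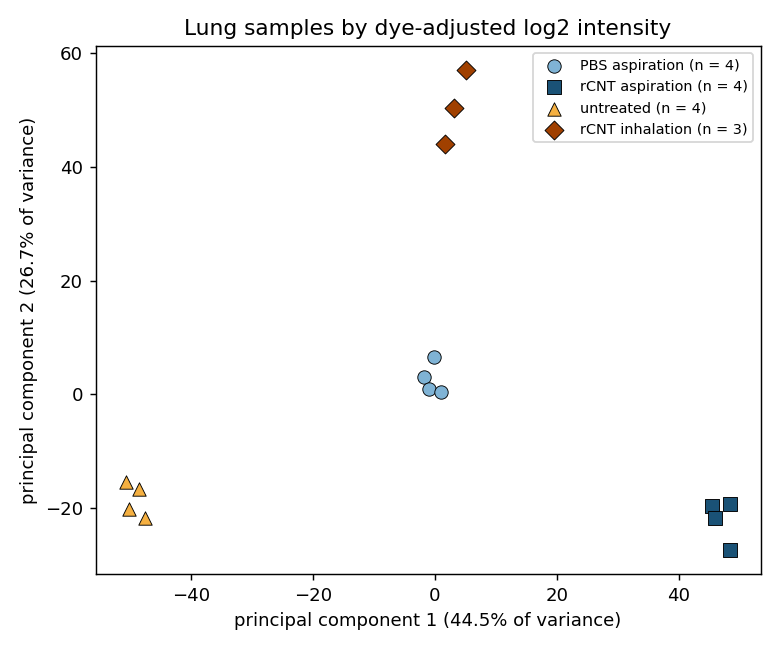
Principal components 1 and 2 (axes in component units, with the percent of variance) of dye-adjusted log2 intensities, 1 point per sample and 1 colour and shape per group. The untreated samples lie at the left, the aspirated rCNT samples at the right, and the inhaled rCNT samples at the top.

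The first comparison addressed the response of the lung to aspirated rCNT against aspirated PBS. Genes of type 2 (allergic) inflammation, chemokine genes and mucus genes rose most. Ccl24, a chemokine that attracts eosinophils, rose by 5.95 ± 0.19 (log2 fold change ± SE, 4 samples per group), and Arg1, the arginase of alternatively activated macrophages, by 5.08 ± 0.12. Clca1, a secreted goblet cell protein, rose by 5.43 ± 0.41, the chemokine gene Ccl8 by 5.19 ± 0.13, and the acute phase gene Saa3 by 5.01 ± 0.19. AA467197 rose by 5.27, the anion exchanger gene Slc26a4 by 4.98 and Fbp1, an enzyme of gluconeogenesis, by 4.97. Among the largest falls were those of Fabp1, a fatty acid binding protein (-3.55 ± 0.12), Pon1 (-2.78 ± 0.10) and Cyp2a4, an oxidase of foreign compounds (-2.74 ± 0.18). For these 11 genes no exposed sample overlapped a PBS sample, and limma's adjusted p lay between 2.59e-13 and 3.44e-08.

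Macrophage and granulocyte genes rose together after aspiration. In the list of alternatively activated macrophages all 20 measured members rose (camera adjusted p = 2.53e-19). Retnla, a secreted protein of type 2 inflammation, rose by 3.95 ± 0.31, and the chitinase-like genes Chil4 and Chil3 by 4.10 and 2.0. Of 21 members of the monocyte and recruited macrophage list 17 rose and 2 fell (adjusted p = 4.72e-12). Among them the complement gene C1qb rose by 2.20, and Mmp12, a macrophage elastase that was not well above background in PBS samples, was at least 8.55-fold higher. Another probe of Mmp12 was 0.77 higher on the log2 scale. Spp1, a matrix protein of macrophages, rose by 2.95. Of 15 members of the classically activated macrophage list 10 rose and 1 fell (adjusted p = 5.89e-05), with Cxcl10 at 4.48 and Cd86 at 1.11. In the eosinophil list 8 of 9 members rose (adjusted p = 5.41e-08), among them Cd300lf by 1.79 and the granule protein gene Prg2 by 2.99, which was well above background in 1 of 4 PBS samples. Of 17 members of the list for eosinophil recruitment and type 2 cytokines 13 rose and 2 fell (adjusted p = 2.67e-10). Ccl7 rose by 4.33 and Ccl11 by 3.44, while Il13ra2, the decoy receptor for interleukin 13, was 0.14 higher and did not pass (adjusted p = 0.294).

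Chemokine, acute phase and defence genes rose as well. Of 17 CC chemokine members 14 rose and 1 fell (adjusted p = 5.02e-13), with Ccl9 at 3.62, Ccl2 at 3.87 and Ccl17 at 3.56. Of 14 CXC chemokine members 10 rose and 2 fell (adjusted p = 9.2e-06). Cxcl1 rose by 3.01, Cxcl3 was at least 3.99-fold higher than in PBS samples, where it was not well above background, and Cxcl5 rose by 4.44, with 1 of 4 PBS samples well above background. Of 19 acute phase members 16 rose and 1 fell (adjusted p = 5.02e-13), with Saa1 at 4.57 and Serpina3n at 2.33. All 29 interferon response members rose (adjusted p = 3.68e-19), among them Oas1a by 2.30 and Ifit1 by 1.77. Of 18 complement members 13 rose and 1 fell (adjusted p = 8.04e-09), with Cfb at 2.09. Of 19 members of the inflammasome and IL-1 list 13 rose and 1 fell (adjusted p = 5.48e-06), with the alarmin gene Il33 at 2.28 and Il1r2 at 1.76. Of 19 eicosanoid members 12 rose and 4 fell (adjusted p = 0.000136), with Tbxas1 at 1.43 and Ptgs1 at 1.42.

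All 34 cell cycle members rose after aspiration (adjusted p = 2.64e-31), among them Cdc20 by 2.66 and Rrm2 by 2.50. Of 19 goblet cell and mucus members 16 rose and 1 fell (adjusted p = 2.71e-11). Agr2, which helps fold mucins, rose by 4.05, the mucin gene Muc5ac by 3.67, and Tff1 was at least 8.80-fold higher than in PBS samples, where it was not well above background. Of 22 members of the list of matrix proteases and their inhibitors 15 rose and 3 fell (adjusted p = 2.62e-07), with Timp1 at 3.21. Of 26 lysosome and phagocytosis members 18 rose and 3 fell (adjusted p = 2.06e-08), with Ctsk at 2.37 and Fcgr2b at 2.13. Of 16 members of the list for xenobiotic metabolism 12 fell and 1 rose (adjusted p = 4.41e-06), with Cyp4b1 at -1.47. These lists and those of the preceding 2 paragraphs, 17 in all, also passed with an estimated correlation, at adjusted p = 0.0133 to 0.0486. Among the genes fixed by name, Fkbp5, a gene induced by glucocorticoids, rose by 0.48.

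Another 12 lists passed with the preset correlation only. Of 24 neutrophil members 13 rose and 2 fell (adjusted p = 1.04e-05, and adjusted p = 0.135 with an estimated correlation), with Ltf at 2.22 and Cd177 at 1.99. S100a8 at 0.51 and S100a9 at 0.24 did not pass (limma adjusted p = 0.115 and 0.482). Of 16 dendritic cell members 11 rose and 1 fell (adjusted p = 4.11e-07, and 0.0536 with an estimated correlation), with Batf3 at 2.18. Of 12 members of the class II antigen presentation list 9 rose (adjusted p = 4.12e-05, and 0.23 with an estimated correlation), with Ctss at 1.55 and H2-DMb1 at 0.90. Of 21 T cell members 8 rose (adjusted p = 0.000481, and 0.376 with an estimated correlation), with Il2ra at 1.44 and Icos at 1.27. Of 29 fibroblast and matrix members 19 rose and 4 fell (adjusted p = 8.06e-07, and 0.0789 with an estimated correlation), with Fn1 at 1.46 and Col1a1 at 1.36. In the alveolar macrophage list 6 of 17 members rose and 5 fell (adjusted p = 0.0373, and 0.282 with an estimated correlation). That call was lost without PBS replicate 4 (0.0594) or without rCNT replicates 1 (0.0603) or 2 (0.0611), with the processed signal (0.0583) and with loess normalisation (0.0653).

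Genes of endothelial, alveolar type 1, club and mesothelial cells fell in the same samples, while the alveolar type 2 list (adjusted p = 0.832) and the ciliated cell list (adjusted p = 0.283) did not pass. Of 23 endothelial members 20 fell (adjusted p = 8.04e-09, and 0.0957 with an estimated correlation), with Kdr at -1.05 (-0.22 by another probe) and Eng at -0.84. Of 15 alveolar type 1 members 13 fell and 1 rose (adjusted p = 6.86e-07, and 0.0705 with an estimated correlation), with Akap5 at -1.24 and Cav1 at -0.95. Of 12 club cell members 9 fell and 2 rose (adjusted p = 0.00669, and 0.201 with an estimated correlation), with Aldh1a1 at -1.20 and Ces1d at -1.08. Of 10 mesothelium members 7 fell and 1 rose (adjusted p = 0.00669, and 0.224 with an estimated correlation), with Upk1b at -1.17 and Rspo1 at -0.88. Of 20 cardiac muscle markers 18 fell (adjusted p = 5.48e-06, and 0.228 with an estimated correlation), with Cox8b at -1.72 and Myh7 at -1.65. Of 14 erythrocyte and platelet members 9 fell and 1 rose (adjusted p = 0.0455, and 0.469 with an estimated correlation), with Alas2 at -1.28 and Hbb-b2 at -1.20. That call was lost without PBS replicates 2 (0.0794) or 3 (0.0838), without aspirated rCNT replicate 1 (0.073), without inhaled rCNT replicate 1 (0.0514) and without untreated replicate 2 (0.0511). It was also lost with the processed signal (0.0512), with only probes well above background in all samples (0.0916), with slide as a block (0.0527), with trend and robust variance (0.142) and with array weights (0.18).

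In total 11924 of 25317 genes passed the threshold after aspiration, of which 5213 were higher and 6711 lower. At least 2-fold higher were 725 and at least 2-fold lower 236. The other 14 of the 43 lists did not pass. The member counts above are over all genes tested. Adjusted over the list alone, they differed in 7 of the 29 lists that passed. There 8 alveolar macrophage, 17 acute phase, 13 eicosanoid and 12 dendritic cell members rose, 3 classically activated and 3 monocyte members fell, and 20 fibroblast members rose and 5 fell.

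**Figure D2:**
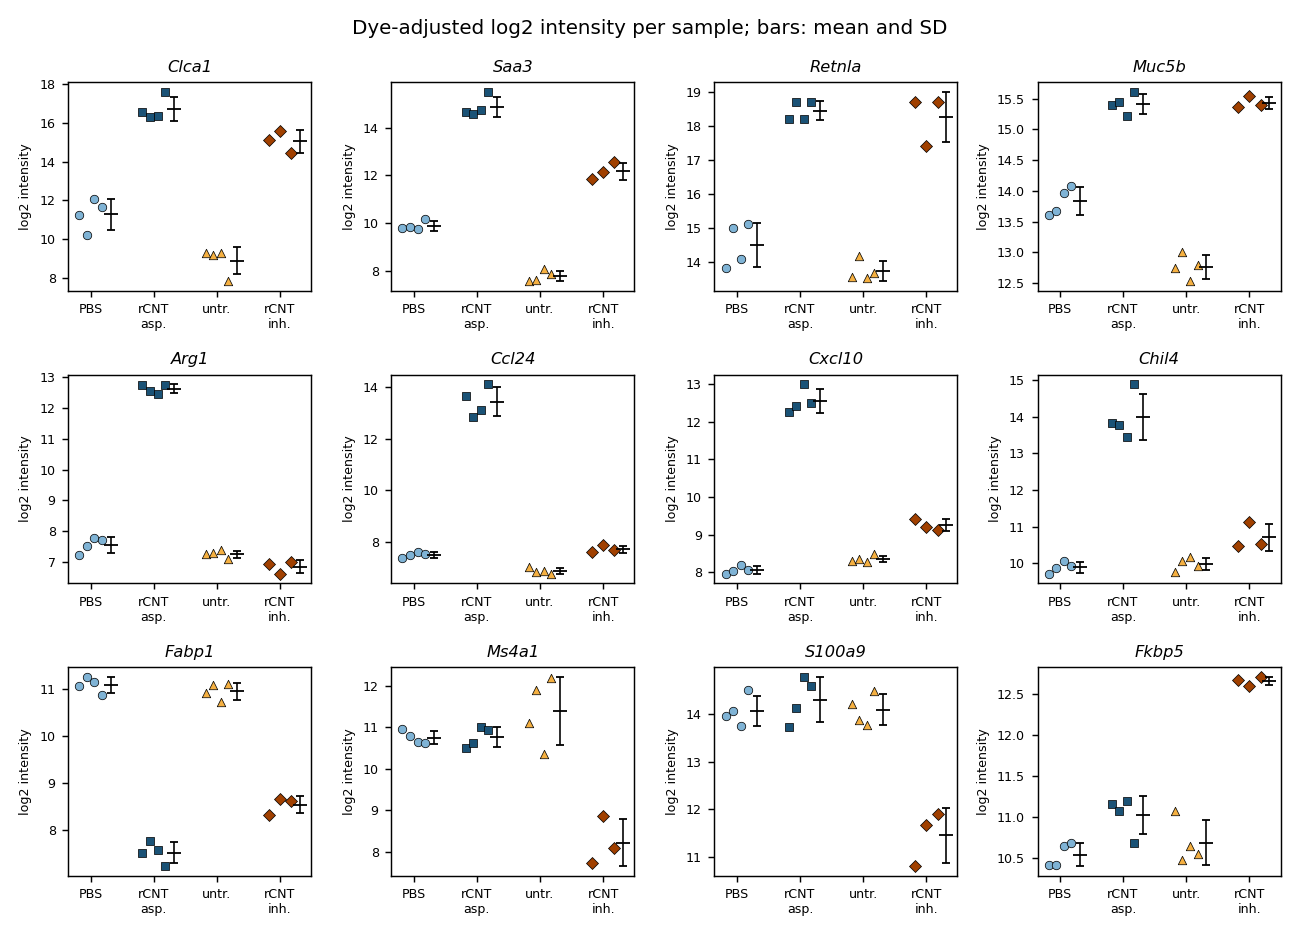
Dye-adjusted log2 intensity (y axis) of 12 named genes in each sample, by group (x axis), with the group mean and SD as bars. Clca1, Saa3, Retnla and Muc5b are higher in exposed than in control samples of both routes. Arg1 rose after aspiration by 5.08 and was at -0.40 after inhalation.

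The second comparison addressed the response to inhaled rCNT against untreated mice. Mucus, acute phase and type 2 genes and nuclear RNAs were among the largest rises. Clca1 rose by 6.18 ± 0.45 (log2 fold change ± SE, 3 exposed and 4 untreated samples), Retnla by 4.54 ± 0.33, Saa3 by 4.39 ± 0.21 and Agr2 by 3.87 ± 0.13. B cell and calprotectin genes fell most. Ms4a1, a surface protein of B cells, was at -3.17 ± 0.34 and Fcmr, a receptor for IgM, at -3.01 ± 0.34, while the neutrophil and monocyte genes S100a9 and S100a8 were at -2.64 and -2.63. The other 4 of the largest rises were in nuclear noncoding RNAs. These were the spliceosomal and nucleolar RNAs Rnu3b1 (4.37 ± 0.23), Rnu2-10 (4.14 ± 0.11) and Rnu1b6 (3.96 ± 0.10) and Neat1 (4.04 ± 0.13), the scaffold of paraspeckles. Against the PBS samples, on another slide, these were at 1.61, 1.81, 0.82 and -0.06. For these 12 genes no exposed sample overlapped an untreated sample, and adjusted p lay between 5.89e-13 and 1.89e-06.

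Goblet and ciliated cell genes rose after inhalation, while the club cell list (adjusted p = 0.148) and the basal cell list (adjusted p = 0.938) did not pass. Of 19 goblet cell and mucus members 15 rose and 1 fell (adjusted p = 2.75e-06, and adjusted p = 0.505 with an estimated correlation). The airway mucin gene Muc5b rose by 2.66 ± 0.13 and Muc5ac by 1.96 ± 0.25. The mean of the list was 1.85 with slide as a block, 1.75 within slide 2 and 1.94 within slide 3, and 1.0 against the PBS samples. Of 16 ciliated cell members 14 rose and 1 fell (adjusted p = 8.3e-07, and 0.505 with an estimated correlation), with Ccdc39 at 2.30 and Rsph1 at 1.69, both parts of motile cilia. Its mean was 1.1 with slide as a block, 1.12 within slide 2 and 1.06 within slide 3. Of 34 cell cycle members 25 rose (adjusted p = 5.98e-09, and 0.505 with an estimated correlation), with Mki67 at 2.22 and Cdc20 at 1.57. Its mean was 0.88 with slide as a block and within each slide.

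Acute phase and CC chemokine genes rose after inhalation, while the CXC chemokine list did not pass (5 of 14 members higher and 3 lower, adjusted p = 0.615). Of 19 acute phase members 18 rose and 1 fell (adjusted p = 1.98e-06, and 0.505 with an estimated correlation), with Lcn2 at 1.90. The list mean was 1.06 with slide as a block, 0.98 within slide 2 and 1.14 within slide 3. Of 17 CC chemokine members 12 rose and 1 fell (adjusted p = 0.000443, and 0.505 with an estimated correlation), with Ccl17 at 2.47, Ccl2 at 2.05 and Ccl9 at 1.35. Here the mean was 0.73 with slide as a block, 0.77 within slide 2 and 0.69 within slide 3. Of 17 members of the list for eosinophil recruitment and type 2 cytokines 10 rose and 2 fell (adjusted p = 0.0243, and 0.621 with an estimated correlation), with Ccl8 at 1.94 and Ccl11 at 1.02. Its mean was 0.65 with slide as a block, 0.61 within slide 2, where it did not pass, and 0.69 within slide 3, and with array weights it was lost (0.0701). Of 20 alternatively activated macrophage members 12 rose and 3 fell (adjusted p = 0.0146, and 0.621 with an estimated correlation). That mean was 0.59 with slide as a block, 0.54 within slide 2, where it did not pass, and 0.64 within slide 3. Against the PBS samples it did not pass either (adjusted p = 0.0844).

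Among the genes fixed by name, Chil3 rose by 1.19, Timp1 by 1.71, Il33 by 0.97 and Spp1 by 0.95 after inhalation. Cxcl1 rose by 2.44 and Cxcl5 by 1.43, each well above background in 2 of 4 untreated samples. Mmp12 was at least 1.55-fold higher than in untreated samples, where it was not well above background. Chil4 rose by 0.73 and Arg1 fell by 0.40. Without exposed replicate 2 these were at 0.45 and -0.24 and Cxcl5 at 1.01, and none of the 3 passed (adjusted p = 0.172, 0.159 and 0.0794). Chil4 was also lost without untreated replicate 1 (0.65, adjusted p = 0.0575), and Arg1 and Chil4 with slide as a block (-0.32 and 0.68, adjusted p = 0.0608 and 0.0516) and with array weights (0.0689 and 0.0598). Arg1 was lost with loess normalisation (0.0559), and Chil4 with median centring (0.144) and with trend and robust variance (0.0516). Within slide 2 Cxcl5 was at 0.68 and did not pass, and Arg1 and Chil4 passed within neither slide. Il13ra2 fell by 0.81 against the untreated samples and was 0.31 higher against the PBS samples.

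Glucocorticoid response genes rose after inhalation. Of 20 members 15 rose and 1 fell (adjusted p = 4.86e-05, and 0.541 with an estimated correlation), with the metallothionein gene Mt2 at 2.08, Fkbp5 at 1.97 and Arrdc2 at 1.23. The list mean was 1.01 with slide as a block, 0.70 within slide 2 and 1.34 within slide 3.

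Lymphocyte and blood cell genes fell in the same samples. The neutrophil list did not pass (5 of 24 members higher and 8 lower, camera adjusted p = 0.9). Its member Ltf rose by 3.22, opposite to the falls of S100a8 and S100a9 given above. Of 17 B cell and plasma cell members 15 fell (adjusted p = 0.000691, and 0.621 with an estimated correlation), among them Fcrla at -2.24 ± 0.26. Of 17 NK and innate lymphoid members 15 fell and 2 rose (adjusted p = 0.000238, and 0.621 with an estimated correlation), with the granzyme genes Gzma at -2.22 and Gzmb at -1.68. Of 21 T cell members 13 fell and 1 rose (adjusted p = 0.00179, and 0.621 with an estimated correlation), with Cd5 at -1.34 and Bcl11b at -1.26. Of 12 thymus and lymph node markers 9 fell and 1 rose (adjusted p = 0.026, and 0.621 with an estimated correlation), with Cd8b1 at -1.30 and Lef1 at -1.05. The thymus and lymph node list was lost with median centring (0.0559), with only probes well above background in all samples (0.0825) and with trend and robust variance (0.0666). Of 12 class II antigen presentation members 10 fell (adjusted p = 0.00373, and 0.621 with an estimated correlation), with H2-DMa at -1.36 and H2-Aa at -1.15. Of 14 erythrocyte and platelet members 12 fell (adjusted p = 0.000851, and 0.621 with an estimated correlation), with Bpgm at -1.19 and Gp1ba, well above background in 2 of 3 exposed samples, at -0.73. The last list did not pass against the PBS samples (adjusted p = 0.102). With slide as a block, within slide 2 and within slide 3 the means were -1.13, -0.97 and -1.29 for B cells, -1.11, -0.96 and -1.26 for NK cells and -0.75, -0.68 and -0.82 for T cells. They were -0.67, -0.63 and -0.71 for thymus and lymph node, -0.85, -0.79 and -0.91 for antigen presentation and -0.81, -0.70 and -0.93 for erythrocytes and platelets.

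Endothelial and matrix genes also fell after inhalation. Of 23 endothelial members 19 fell and 1 rose (adjusted p = 8.83e-05, and 0.621 with an estimated correlation), with Aplnr at -1.79 and Sox18 at -1.22. Of 29 fibroblast and matrix members 20 fell and 3 rose (adjusted p = 0.00937, and 0.621 with an estimated correlation), with the crosslinking enzyme Loxl1 at -1.36 and Fbln2 at -0.71. The means were -0.68 and -0.28 with slide as a block, -0.84 and -0.40 within slide 2 and -0.50 and -0.15 within slide 3. The fibroblast list did not pass within slide 3 (adjusted p = 0.203) or against the PBS samples (adjusted p = 0.453).

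In total 15398 of 25317 genes passed after inhalation, 7180 higher (46.6%) and 8218 lower. At least 2-fold higher were 1051 and at least 2-fold lower 450. With each channel centred on its median instead of quantile-normalised, 27.5% of the calls were higher and the median of all genes lay at -0.15, so directions of small changes depend on the scaling. With slide as a block 15223 genes passed, within slide 2 (1 exposed and 3 untreated samples) 12331 and within slide 3 (2 and 1) 10782, a lone sample being assumed to vary like the others. Of the 1501 genes changed at least 2-fold, all 1501 kept their direction within slide 2 and 1500 within slide 3. These genes were picked from the same samples, so kept directions were nearly given and show little about slide. Adjusted over the list alone the member counts of the 16 lists that passed were those over all genes tested, except 11 antigen presentation members lower and 16 glucocorticoid members higher. The other 27 lists did not pass, and with an estimated correlation 0 of 43 lists passed.

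**Figure D3:**
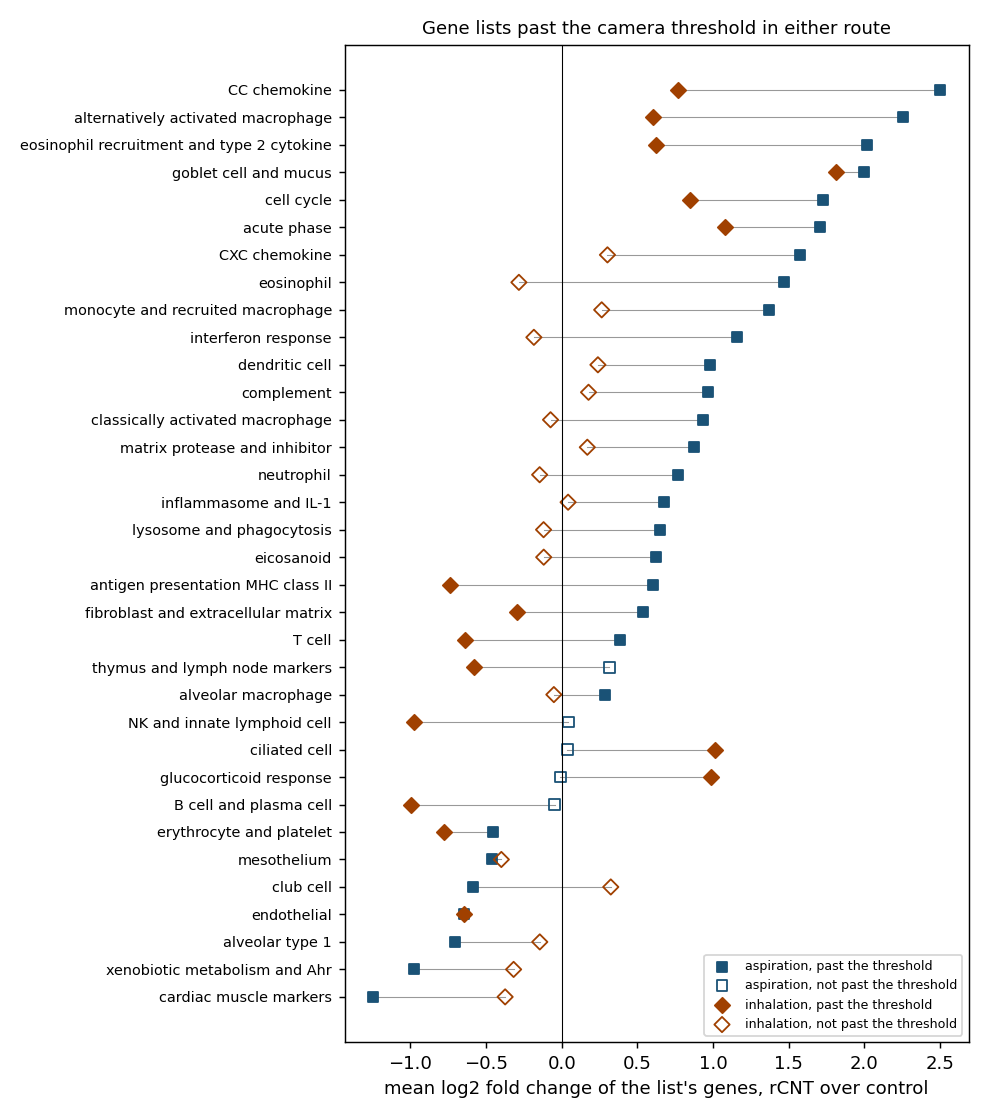
Mean log2 fold change (x axis) of the members of each gene list that passed camera in either route (y axis), for aspiration (squares) and inhalation (diamonds). Filled symbols passed with the preset correlation. The goblet cell, acute phase and cell cycle lists lie above 0 for both routes, and the B cell and NK cell lists lie below 0 for inhalation.

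Nuclear noncoding RNA was lower in the untreated samples than in every other group, and this stands beside every inhalation result. Over 11 such RNAs, chosen after the rises above were seen, the median log2 fold change was 2.72 after inhalation and -0.06 after aspiration. Each sample's median over these RNAs was 8.2 to 8.5 in untreated samples, 10.2 to 10.5 in PBS samples, 10.3 to 10.7 in aspirated rCNT samples and 11.6 to 11.8 in inhaled rCNT samples. Inhaled rCNT samples lay above PBS samples by a median log2 value of 0.73, so which group stands apart is not settled. With the PBS samples in place of the untreated ones, 13972 genes and 17 lists passed for inhalation. These were not all the lists called against untreated mice. The eosinophil (mean -0.72, camera adjusted p = 0.00574) and interferon response lists (-0.23, 0.0222) passed as lower only here. So did the cardiac muscle (-1.43, 5.06e-06) and adipose tissue lists (-0.70, 0.0431). The alternatively activated macrophage, fibroblast and erythrocyte lists no longer passed (0.0844, 0.453 and 0.102). Several changes were then smaller while still past the threshold, with Clca1 at 3.77, Saa3 at 2.30, Muc5b at 1.60, Ccdc39 at 1.35, Ccl2 at 1.05, Timp1 at 0.60, Arrdc2 at 0.54 and Ccl11 at 0.45. Lower values of this kind were -0.89 for Gzmb, -0.87 for H2-DMa, -0.68 for Bpgm, -0.62 for Lef1, -0.61 for Loxl1, -0.48 for Sox18 and -0.34 for Gp1ba, and the endothelial list had a mean of -0.40. Arg1 was at -0.71. Slide and kind of control differ between these control groups.

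**Figure D4:**
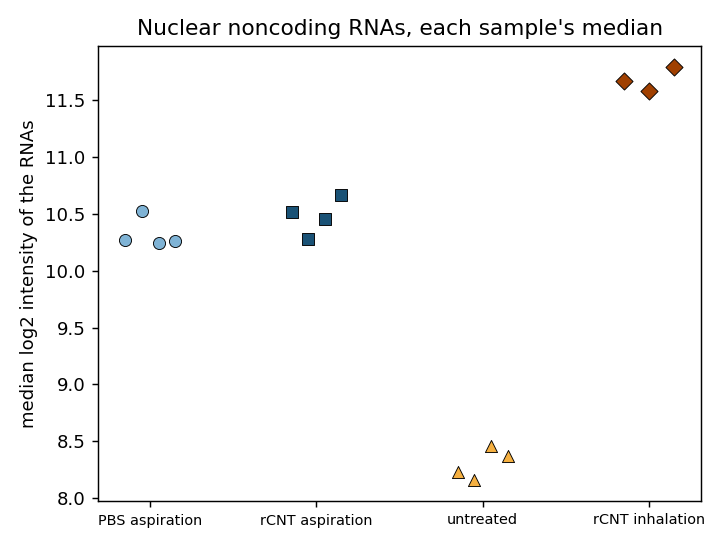
Median log2 intensity (y axis) over 11 nuclear noncoding RNAs in each sample, by group (x axis). The 4 untreated samples lie at 8.2 to 8.5, below all other samples.

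The third comparison addressed whether the response to rCNT differed by route, as the aspiration effect minus the inhalation effect. The amount of rCNT taken up by inhalation is not given, so dose, slide and kind of control cannot be told apart from route. Macrophage, granulocyte and chemokine genes were among the 6 most positive differences. Arg1 differed by 5.47 ± 0.18, with 5.08 after aspiration and -0.40 after inhalation, and Ccl24 by 5.11 ± 0.28, with 5.95 and 0.84. Cebpe, a transcription factor of granulocytes, differed by 4.37 ± 0.21 (3.55 and -0.82, well above background in 1 of 3 inhaled rCNT samples), the B cell chemokine gene Cxcl13 by 4.01 ± 0.49 (4.04 and 0.04, the latter not past the threshold), Cxcl10 by 3.59 ± 0.18 (4.48 and 0.89) and Fbp1 by 3.42 ± 0.24 (4.97 and 1.55). Nuclear RNAs led the opposite end. The differences were -4.68 ± 0.17 for Neat1, -4.43 ± 0.14 for Rnu1b6, -4.04 ± 0.31 for Rnu3b1 and -4.00 ± 0.15 for Rnu2-10. AW549542 differed by -4.00 ± 0.15, with -1.29 after aspiration and 2.71 after inhalation, and Rgs11, a regulator of G protein signalling, by -3.43 ± 0.26, with -0.79 and 2.64. Against the PBS samples the inhalation values of AW549542 and Rgs11 were 0.03 and -0.05, and that of Ccl24 was 0.23, none past the threshold (adjusted p = 0.844, 0.838 and 0.37). Adjusted p of these 12 genes lay between 1.17e-11 and 4.73e-06.

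Of 34 lists that passed in either route, 29 differed between routes with the preset correlation and none with an estimated one. The interferon response list was higher after aspiration, where 27 of 29 members differed that way (adjusted p = 1.47e-11, and adjusted p = 0.154 with an estimated correlation). All 12 class II antigen presentation members differed in that direction (adjusted p = 6.06e-06, and 0.246 with an estimated correlation). H2-Aa, an antigen presenting chain, rose by 0.79 after aspiration and fell by 1.15 after inhalation. In the opposite direction went 14 of 16 ciliated cell members (adjusted p = 2.73e-06, and 0.207 with an estimated correlation) and 14 of 20 glucocorticoid response members (adjusted p = 0.000755, and 0.286 with an estimated correlation). Goblet cell and mucus genes as a list did not differ past the threshold (adjusted p = 0.391), nor did endothelial genes (adjusted p = 0.768). Their members differed in both directions, so this does not show an equal response. Of 19 goblet members 9 were higher after aspiration and 6 lower, and of 23 endothelial members 6 and 6. Of the 104 named genes 90 differed. Among the 14 that did not pass, the difference was 0.18 ± 0.18 for Agr2, -0.74 ± 0.61 for Clca1, -0.59 ± 0.45 for Retnla and 0.30 ± 0.14 for Mki67. Retnla had the highest value of all genes in 4 exposed samples, where quantile normalisation sets a ceiling. In total 14422 genes differed, 7194 of them (49.9%) with the higher value after aspiration. With median centring that share was 69.3% and the median of all genes lay at 0.14.

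**Figure D5:**
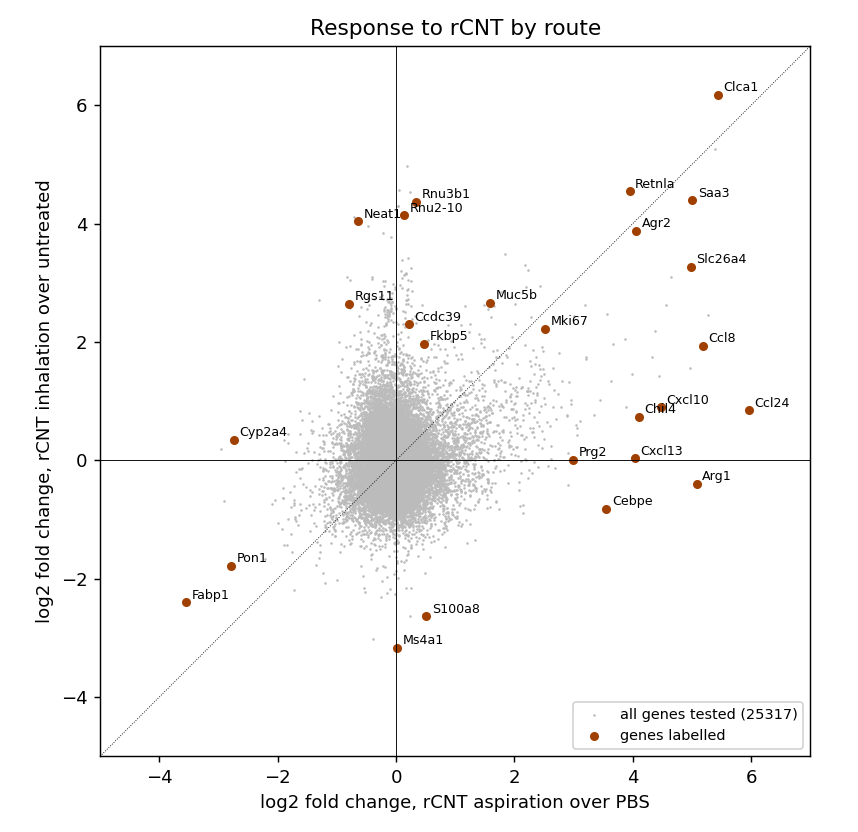
Log2 fold change after inhalation (y axis) against that after aspiration (x axis) for each of 25317 genes tested (grey), with named genes labelled and the line of equal change dotted. Clca1, Retnla and Saa3 lie high on both axes, Arg1 and Ccl24 only on the x axis, and Neat1 high on the y axis only.

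Across all genes tested the log2 fold changes of the 2 routes correlated weakly (Pearson's r = 0.148, Spearman's rho = 0.007), and genes are not independent replicates. Over the 961 genes changed at least 2-fold after aspiration r was 0.578, and over the 1501 changed at least 2-fold after inhalation it was 0.275. The routes share no control sample. With the PBS samples split between both routes as controls, an alternative chosen after the untreated samples were seen to stand apart, r was 0.276. Past the threshold in both routes were 4115 genes with the same sign and 3951 with opposite signs. Independent lists would give 1478 genes higher in both and 2178 lower in both, against 1603 and 2512 observed. Opposite signs exceeded independence to a similar degree, with 1865 genes higher after aspiration and lower after inhalation (1692 for independent lists) and 2086 the other way (1903). At least 2-fold higher in both routes were 168 genes (30.1 for independent lists), among them Clca1, Retnla, Saa3, Agr2, Slc26a4 and Ltf, and at least 2-fold lower 42 (4.2), among them Fabp1 and Pon1. At least 2-fold in opposite directions were 8 (12.9) and 3 (9.8).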

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

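The tests of slide, of a common rCNT effect and of sample handling for the nuclear RNAs, both tests for the cardiac muscle genes, their group means, the clock genes against PBS samples and the differences with PBS controls were chosen after the results they measure were seen.

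A sample far from the other samples of its group singled out 25 of 414 values tested, where the gap to the nearest sample is divided by the range of the 4 samples. Chance gives about 1 in 20. In PBS samples the ratio was 0.873 for Ccl7, 0.868 for Cxcl5, 0.862 for Mki67 and 0.939 for the mean of the neutrophil list, all with replicate 4 highest, and 0.831 for the cardiac muscle list with replicate 4 lowest. It was 0.875 for Ctss with replicate 3 lowest and 0.96 for Pon1 with replicate 2 highest. For list means it was 0.907 for alternatively activated macrophages and 0.854 for CXC chemokines with replicate 1 lowest, and 0.903 for the fibroblast list with replicate 2 lowest. In aspirated rCNT samples replicate 4 was highest for Cxcl5 (0.883), Lcn2 (0.922), Loxl1 (0.876) and the acute phase (0.84), goblet cell (0.861), fibroblast (0.921) and inflammasome (0.862) lists. There replicate 1 was lowest for Oas1a (0.851), replicate 2 highest for Upk1b (0.9) and replicate 3 lowest for the endothelial list (0.876). In untreated samples Ccl2 was lowest in replicate 2 (0.837), Cd300lf lowest (0.956) and Ccl8 highest (0.851) in replicate 3, Clca1 lowest in replicate 4 (0.927) and Muc5ac lowest in replicate 1 (0.871).

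A difference between routes, tested as the aspiration effect minus the inhalation effect, passed the threshold for 90 of 104 named genes. Chemokine genes were higher after aspiration: Ccl24 5.11, Cxcl13 4.01, Cxcl10 3.59, Ccl8 3.25, Cxcl5 3.01, Ccl7 2.58, Ccl11 2.42, Ccl9 2.28, Ccl2 1.81, Cxcl3 1.80 and Ccl17 1.09. So were macrophage, eosinophil and dendritic genes: Arg1 5.47, Chil4 3.37, Prg2 2.98, Mmp12 2.45, C1qb 2.19, Spp1 2.01, Ctss 1.91, Fcgr2b 1.70, Tbxas1 1.54, Batf3 1.22, Chil3 0.82, Cd86 0.71, Ctsk 0.63 and Ptgs1 0.58. The differences of Mmp12, Prg2, Tff1, Cxcl3, Cxcl5, Cebpe, Il1r2 and Gp1ba are not exact, because some of their groups had samples not well above background. Granulocyte and acute phase genes were at Cebpe 4.37, S100a8 3.15, S100a9 2.87, Il1r2 1.94, Saa1 1.94, Serpina3n 1.60, Cfb 1.51, Il33 1.31, Cd177 1.26, Il13ra2 0.95 and Ltf -1.0, of which the last 2 turned with PBS samples as controls of both routes (-0.17 and 0.29). Interferon and antigen presentation genes were at Oas1a 2.52, H2-DMa 2.01, H2-Aa 1.94, Ifit1 1.62 and H2-DMb1 0.84.

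Lymphocyte genes were at Ms4a1 3.20, Fcmr 2.63, Fcrla 2.08, Cd5 2.05, Gzmb 1.85, Gzma 1.70, Il2ra 1.53, Bcl11b 1.45, Icos 1.24 and Cd8b1 1.14, and the blood genes Bpgm at 0.86 and Gp1ba at 0.45. Epithelial and mucus genes were at AA467197 2.81, Tff1 2.58, Muc5ac 1.71, Slc26a4 1.71, Ces1d -0.62, Cav1 -0.93, Muc5b -1.08, Rsph1 -1.16, Aldh1a1 -1.22, Akap5 -1.45 and Ccdc39 -2.09. Matrix, vessel and mesothelial genes were at Col1a1 1.85, Loxl1 1.59, Timp1 1.51, Fn1 1.27, Aplnr 1.19, Fbln2 0.84, Sox18 0.56, Kdr -0.52 and Rspo1 -1.67, and cardiac genes at Myh7 -0.72 and Cox8b -1.04. With PBS samples as controls of both routes Col1a1 was at 1.13, Loxl1 at 0.83, Timp1 at 2.61 and Rspo1 at -0.77. Sox18 then turned to -0.18, which did not pass, and the others kept direction and call. Metabolic and cell cycle genes were at Fbp1 3.42, Cdc20 1.09, Rrm2 1.04, Cyp4b1 -0.71, Pon1 -1.0, Fabp1 -1.15 and Cyp2a4 -3.09. The glucocorticoid response genes Fkbp5 and Arrdc2 were at -1.49 and -1.59. Nuclear RNAs and others were at Rgs11 -3.43, AW549542 -4.00, Rnu2-10 -4.00, Rnu3b1 -4.04, Rnu1b6 -4.43 and Neat1 -4.68. With PBS samples as controls of both routes Rgs11 was at -0.74, AW549542 at -1.32 and Neat1 at -0.58. Rnu2-10 was then at -1.67, Rnu3b1 at -1.28 and Rnu1b6 at -1.30.

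The same test passed for 29 lists, of which 23 were higher after aspiration, and with an estimated correlation it passed for none (lowest adjusted p = 0.117). Their mean differences were 1.75 for eosinophils, 1.73 for CC chemokines, 1.65 for alternatively activated macrophages, 1.40 for eosinophil recruitment, 1.35 for antigen presentation, 1.34 for the interferon response, 1.27 for CXC chemokines, 1.11 for monocytes, 1.02 for T cells and for NK cells, and 1.01 for classically activated macrophages. They were 0.95 for B cells, 0.92 for neutrophils, 0.89 for thymus and lymph node, 0.88 for the cell cycle, 0.83 for fibroblasts, 0.79 for complement, 0.77 for lysosomes, 0.74 for dendritic cells and for eicosanoids, 0.70 for matrix proteases, 0.64 for the inflammasome and 0.63 for the acute phase. Lower were alveolar type 1 (-0.56), xenobiotic metabolism (-0.66), cardiac muscle (-0.87), club cells (-0.91), ciliated cells (-0.98) and the glucocorticoid response (-1.0).

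Nuclear noncoding RNAs were lower in untreated samples than after inhalation of rCNT, by a median log2 value of 2.72 over 11 RNAs. Slide and dye are argued against, since the lowest of the medians on the shared array and within each slide was 2.63. On the shared array dye and group go together, so that value rests on the fitted dye term. Cy3 samples of 1 slide lay apart too. Sample medians were 11.66 (inhaled rCNT replicate 1) and 8.23 (untreated replicate 1) on slide 2. On slide 3 they were 11.79 (inhaled rCNT replicate 3) and 8.37 (untreated replicate 4). The RNAs were chosen from these same samples. An effect of rCNT common to both routes is argued against by the median of -0.06 after aspiration (bootstrap interval over the RNAs -0.22 to 0.14). RNA preparation or handling of the untreated mice stays open. The untreated samples lay at -2.33 against PBS samples, but slide and kind of control differ as well, and an effect of inhaled rCNT alone was not tested.

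B cell and NK cell genes were lower and glucocorticoid response genes higher after inhalation. These 3 lists passed camera with the preset correlation only (adjusted p = 0.621, 0.621 and 0.541 with an estimated one). Less blood in the exposed lungs stays open, because B cell and NK members lay at a mean of -0.98 and erythrocyte and platelet members at -0.78, a difference of -0.21 (permutation p = 0.374 over members, which are not independent). A different time of day of collection stays open, because clock genes of opposite phase moved apart by 1.92 (exact permutation p = 0.0364 over 55 arrangements of members, 0.0485 adjusted over 4 tests), although after aspiration they lay apart by -0.78 (exact permutation p = 0.0182, adjusted 0.0364), 1 of the 2 phases has only 2 members and the circadian clock list did not pass (adjusted p = 0.148). With PBS samples as controls all 3 lists passed in the same direction while the clock genes lay apart by 0.08, but these samples lie on another slide, so untreated samples standing apart cannot be told apart from an exposure effect. Against PBS samples the erythrocyte and platelet mean was -0.37 (camera adjusted p = 0.102), with B cells at -0.87 and NK cells at -0.695. A response to inhaled rCNT or to the stress of exposure also stays open, untested. So does less carried-along thymus or lymph node tissue. Its list fell to a mean of -0.58 (camera adjusted p = 0.026). Against PBS samples that mean was -0.67 (camera adjusted p = 0.00224).

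Cardiac muscle genes were lower after aspiration of rCNT, with 18 of 20 members past the threshold. Dilution of lung tissue by incoming cells is argued against as the whole cause, since the cardiac median lay at -1.30 below that of members of 5 resident cell lists (permutation p = 1e-05, the smallest that 100000 resamples can give, with members not independent). The pooled lists include the fibroblast list, whose median rose by 0.555, which widens that gap. Alveolar type 1 and endothelial members had medians of -0.77 and -0.70, nearer to the cardiac median of -1.49. Less cardiac muscle in the exposed samples stays open, as does lower expression within such cells, which the joint fall of 18 members does not separate. Of the 4 groups PBS samples had the highest mean for 18 of 20 members (Myh6 15.38 against 13.50 after aspirated rCNT, 13.18 in untreated and 13.17 after inhaled rCNT), but Myh7 was at 10.90 in untreated and 10.91 in PBS samples and 7 members also fell after inhalation, with slide confounded.

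Other splits of the samples test whether chance can be excluded, and each count of splits below includes the real one. For the genes called after aspiration, chance assignment of these samples is argued against. The real split gave 11924 and the highest other 0, with 1 of 35 splits as large, the lowest share possible. Other splits mix samples that differ, which widens the spread, so the 0 itself says little. Samples may be pools, so chance between mice is not covered. For inhalation it is argued against too, with the same limits (15398 against 9531, 1 of 35). There the high splits keep the 3 exposed samples together and add 1 untreated sample to them. For the counts of lists chance cannot be excluded this way, as 11 of 35 splits gave as many after aspiration (29 against 31) and 8 of 35 after inhalation (16 against 20). The high aspiration splits exchange 1 sample of each group, and splits that exchange more gave at most 8 lists, against at most 16 for inhalation. With an estimated correlation the aspiration split gave 17 lists and the highest other 0. Of 100 joint relabellings, only the real one gave as many genes differing between routes (14422 against 8855). The relabelling with 8855 kept the true inhalation groups and so holds the inhalation effect. Most others mix exposed and control samples in both routes and stand for no effect. None stands for equal effects in both routes. Chance is therefore not excluded for the difference between routes. For the genes shared with the same sign 1 of 100 gave as many (4115 against 0), but every other split of the aspiration samples called 0 genes, so this shows nothing about sharing. For the correlation chance cannot be excluded (0.148 against 0.608, 38 of 100).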

How the results depend on the processing

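The PBS controls, the PBS samples split between the routes, the fits within a slide and the 2-fold overlap were chosen after seeing the data. Genes named for either route or for the difference kept direction and call in 2262 pairs of gene and setting, lost the call in 12 and turned in 2. With a sample left out they kept it in 2006 and lost it in 4. Called lists kept it in 750 and lost it in 18, and with a sample left out kept it in 667 and lost it in 8. With PBS samples as inhalation controls Il13ra2 turned from -0.81 to 0.307 and Neat1 from 4.04 to -0.056 (adjusted p = 0.73), as did Rgs11, named for the difference, from 2.64 to -0.05 (0.838), and the cause was not tested. Of the 90 differences between routes 3 then turned, none past the threshold (Ltf 0.29, Il13ra2 -0.17 and Sox18 -0.18), and those of Muc5b (-0.02) and Gp1ba (0.06) no longer passed. The others kept direction and call, but sizes moved both ways. Neat1 went from -4.68 to -0.58, Rgs11 from -3.43 to -0.74, Cyp2a4 from -3.09 to -1.69 and Timp1 from 1.51 to 2.61. Camera with an estimated correlation called 17 lists after aspiration and 0 after inhalation, where fry called 28. With the PBS samples so split the correlation of the responses was 0.276. Requiring at least 2-fold in both routes, with the controls of the report, left 210 same-sign genes. Across the planned settings the genes called numbered 9218 (median centring) to 14257 (array weights) for aspiration, 13626 to 16015 for inhalation and 12788 to 15592 for the difference. The correlation was 0.136 to 0.179 and the same-sign genes 2981 to 4986. Leaving out each sample in turn gave 10438 to 12338, 14063 to 15432 and 13515 to 14381 genes, correlations of 0.134 to 0.17, 3647 to 4128 same-sign genes, and 28 to 31 and 16 to 17 lists. Replicate numbers as a block gave 11686, 14609 and 13923 genes, and the alveolar macrophage list did not pass (adjusted p = 0.0582). The same numbers correlated at -0.136 to 0.286, and 3 of 7 samples correlated best with their own number, so the numbers do not pair the samples. The array as a random block gave no value, because 1 of 14 arrays holds more than 1 sample. Signal over background limits fold changes of genes dim in a group, which are lower bounds.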

Other observations

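The lists and genes of this part were chosen after their values were seen. They are given as values, since a test on genes so chosen would show nothing. Of 12 measured genes that drive multiciliated cell differentiation, 12 rose after inhalation, and 6 rose and 1 fell after aspiration. Foxn4 rose by 3.29 after inhalation and 2.17 after aspiration, Deup1, which builds centrioles in such cells, by 2.93 and 2.19, and Ccno by 2.64 and 2.01. Ccdc78 rose by 2.26 after inhalation and was 0.15 higher after aspiration, where it did not pass. Mcidas was at 0.83 after inhalation and at -0.39 after aspiration.

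Of 13 measured genes of macrophage fusion, known from osteoclasts and giant cells, 10 rose and 1 fell after aspiration, with the fusion genes Ocstamp at 2.91 and Dcstamp at 2.73 and the receptor gene Trem2 at 2.65. After inhalation 6 rose and 4 fell, with Dcstamp at 1.12, Trem2 at 0.90 and Ocstamp at 0.13, which did not pass.

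The circadian clock list passed in neither route (adjusted p = 0.148 after inhalation and 0.283 after aspiration) nor in their difference (0.0766). Single members changed. After inhalation Per1 rose by 1.26, Per2 by 1.61, Per3 by 1.88, Ciart by 1.78 and Cry2 by 1.41, while Arntl was at -1.85 and Nr1d1 at -0.72, the latter not past the threshold. After aspiration Per1 was at -0.96 and Cry2 at -0.81, while Nfil3 rose by 1.60 and Bhlhe40 by 1.08. Arntl at 0.13 and Clock at -0.22 did not pass after aspiration.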
